A study of Mus musculus with 14 samples.

How the data were processed

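RNA was sequenced from 14 sorted mouse cell samples: 8 of regulatory T (Treg) cells from skin and 6 of hair follicle stem cells (HFSC), the CD34-positive, integrin alpha 6-high cells of the follicle. Per the labels' protocols, the cells were sorted by flow cytometry from wild-type mice (GR WT) and from mice whose Foxp3-driven Cre deletes a floxed glucocorticoid receptor gene in Treg cells (GR KO). Treg cells were taken 1 day, and HFSC 4 days, after hair depilation. Libraries were made with a stranded mRNA kit, per the labels' protocols.

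The submitters' processing notes name FastQC, Trim Galore, STAR, HOMER and the mouse build mm10. Versions, settings and whether counting used the strand are not given in the sources used here, so reads of overlapping antisense genes and of near-identical copies may be split or shared. The authors deposited 1 table per cell type with TPM (length-scaled transcript abundance) per sample and, per the file headers, 1 RefSeq transcript and its length for each of 24537 gene symbols. Both tables hold the same kind of value but were made separately, so tests were run within a table, and levels set across tables are descriptive. The deposited rows summed to 649917 to 668742 TPM per Treg library and to 639752 to 645251 TPM per HFSC library. A symbol that began with a stray quotation mark was read without it. Treg column headers shared 1 lane label, so no lane split could be made. HFSC columns carried a prefix that the labels do not explain and were matched by table, genotype and number.

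TPM times transcript length was a whole multiple of 1 amount per library within 0.1 of a tag for 100% of the low values tested, so whole tags could be recovered. By that count, the Treg libraries held 9.2 to 14.5 M tags and the HFSC libraries 4.5 to 8.0 M, with WT replicate 1 the shallowest HFSC library. Between 75.9% and 83.9% of the recovered tags per gene were even numbers, so both mates of a pair seem to have been counted, and tags are not independent molecules. For a transcript of 2000 bases, 3 tags corresponded to 0.138 to 0.207 TPM in Treg libraries and 0.308 to 0.515 TPM in HFSC libraries. These floors cover counting error only. Replicates of a group differed by 2.74 to 16.4 times the sampling noise (chi-square per degree of freedom over genes, on tags halved to read pairs), so no library looked like a copy of another. The labels do not say that each replicate is a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

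Groups and replicate numbers were taken from the sample titles. Within each table, genes with a mean of at least 1 TPM were fitted with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trended prior and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. Fold changes are on that scale and understate the change of genes near 1 TPM. Nr3c1, which encodes the receptor, and Tgfb3 were also tested by an exact permutation test of the mean log2 value. A total of 38 gene lists with 573 entries covered pathways, cell states and cell types that a skin sort could let in. After matching older symbols, 10 entries had no row. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01. Beside it stand camera with an estimated correlation and fry, which asks whether the members move one way without comparing them with other genes. The number of members past 0.05 is given adjusted over all genes and adjusted over the list alone.

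The samples, tests, gene lists and the rule for named genes were fixed before the data were examined. An exception is the permutation test of Tgfb3, since the plan held that test for Nr3c1 only. Named genes are a fixed set per table, the 8 higher and 8 lower genes with the largest change among those past the threshold, with at least 5 TPM in a group and no overlap between groups, and up to 4 members of each described list, those with the smallest p. Places left open by too few passing genes went to the smallest p values, named as not past the threshold. Predicted or unnamed loci, small RNAs, ribosomal pseudogenes and antigen receptor segments were left out of the ranked part. Genes outside this rule are named as chosen after their values were seen.

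The fit was tested on simulated libraries drawn from the real tag means and depths, with 200 changed genes and a biological coefficient of variation of 12.7% for Treg and 12.1% for HFSC. Over 11538 genes of the simulated Treg comparison it recovered 31.8% of 1.5-fold, 85.7% of 2-fold and 98.4% of 4-fold changes. Over 12448 genes of the simulated HFSC comparison it recovered 9.2%, 76.1% and 95.4%. Calls on unchanged genes numbered 6 and 8, in that order. The simulation gave all genes of a table the same coefficient of variation and drew them independently. Real genes differ in spread and can move together, so these rates need not hold for the real libraries.

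Alternatives covered the pseudocount, the filter on low values, quantile and median ratio scaling, sample weights, a robust prior, a threshold of 0.1, the replicate number as a block and each library left out in turn. Chosen after seeing the data were limma voom on the recovered tags, a Treg fit without genes at least 5 times higher in HFSC than in the Treg KO libraries, and fits without small RNA genes. Figures were drawn with matplotlib 3.10.9, and tags were recovered with Python 3.11.15.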

Results

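Gene expression was measured in skin Treg cells 1 day after hair depilation (3 GR WT and 5 GR KO libraries) and in HFSC 4 days after depilation (3 and 3). Depilation starts a new hair growth cycle. By design, the glucocorticoid receptor gene Nr3c1 is deleted in Foxp3-expressing cells of the GR KO mice. The Treg comparison thus reads the cells targeted for deletion, and the HFSC comparison reads stem cells that are not targeted. The study's title frames both by the role of glucocorticoid signalling in Treg cells for stem cell activation and hair growth. Depth was 9.2 to 14.5 M tags per Treg library and 4.5 to 8.0 M per HFSC library.

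Nr3c1 (NM_008173, mm10 chromosome 18, 39410545 to 39487245, minus strand) stood at 129.5 ± 27.3 TPM in Treg GR KO (SD, n = 5) and 211 ± 35.3 TPM in Treg GR WT (SD, n = 3), which is 61.3% of the WT mean. The log2 fold change was -0.71 (SE 0.17, limma adjusted p = 0.0722), the groups overlapped, and the exact two-sided permutation p was 0.0536 over 56 assignments, with 0.0179 the smallest possible. A value summed over the transcript need not fall further where only some exons are deleted. The adjusted p passed without KO replicate 4 (0.027), with median ratio scaling (0.0448), with voom (0.0195) and without small RNA genes (0.0312). It reached 0.117 with no filter on low values, 0.15 without KO replicate 2, 0.162 without WT replicate 2 and 0.276 without WT replicate 3. In HFSC, Nr3c1 was at 43.6 ± 6.89 TPM in KO and 41.6 ± 7.07 TPM in WT (SD, n = 3 each, exact two-sided permutation p = 0.8, smallest possible 0.1).

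In Treg cells, transcripts of glucocorticoid receptor target genes were lower in GR KO. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, fell to 226 ± 22.6 TPM from 431 ± 41.8 TPM (SD, n = 5 and 3, log2 fold change -0.93, SE 0.11, adjusted p = 0.00214). The chemokine receptor gene Cxcr4 fell to 307 ± 34.3 from 727 ± 50.7 TPM (log2 -1.24, SE 0.10, adjusted p = 0.000924), and the interleukin 7 receptor gene Il7r to 258 ± 13.7 from 545 ± 107 TPM (log2 -1.06, SE 0.12, adjusted p = 0.00214). The metallothionein gene Mt1 fell from 133 ± 23.5 to 61.3 ± 18.9 TPM (adjusted p = 0.042), a call lost without KO replicate 1, 3 or 5 or WT replicate 1 or 3 and in 6 of 11 other settings, median ratio and quantile scaling among them. Of 22 tested targets, 4 fell over all genes and 9 when adjusted over the list alone, and none rose. The list fell by camera (adjusted p = 7.78e-07) and by fry (adjusted p = 0.00527), with adjusted p = 0.0747 with an estimated correlation. Its median of -0.30 was -0.48 without WT replicate 1 and -0.24 without WT replicate 3. Fkbp5, another target, was at 26.4 ± 3.66 in KO and 42.7 ± 8.51 TPM in WT and did not pass (adjusted p = 0.0793).

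**Figure D1:**
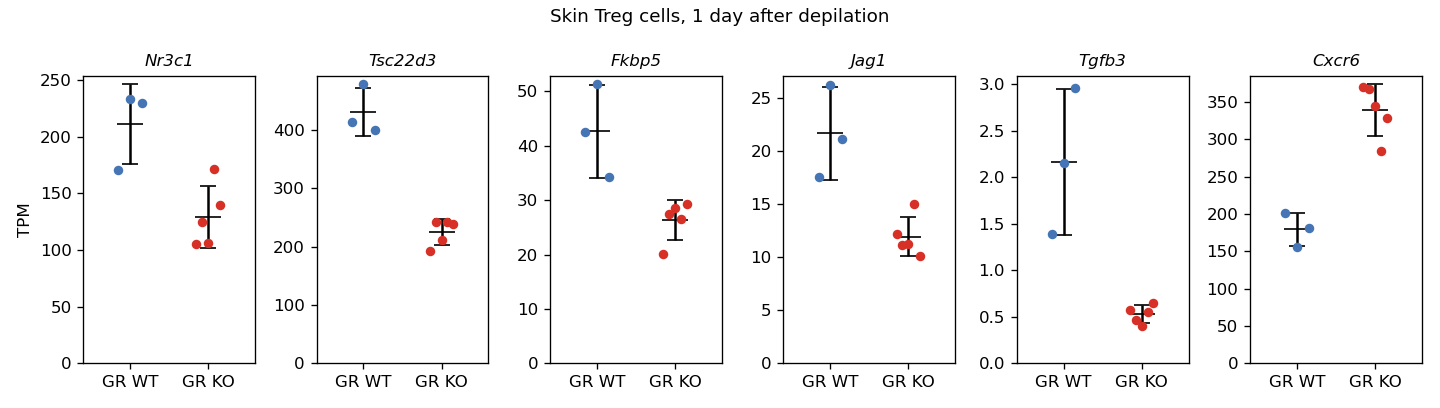
Transcript levels in TPM (y axis) of 6 genes in each skin Treg library, with GR WT in blue (n = 3) and GR KO in red (n = 5), where bars give the mean and SD. Tsc22d3, Fkbp5, Jag1 and Tgfb3 lie lower in every KO library than in every WT library, Cxcr6 lies higher, and Nr3c1 overlaps.

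Transcripts of Treg identity genes differed little between the groups. Of 16 core Treg genes, 1 fell over all genes and 1 adjusted over the list alone, Il2ra, the interleukin 2 receptor alpha chain gene (330.1 ± 10.95 in KO, 485 ± 33.4 TPM in WT, log2 -0.55, SE 0.08, adjusted p = 0.00575). The list did not pass camera (adjusted p = 0.0887), and Foxp3, the lineage factor gene, was at 171 ± 29.1 and 227 ± 61.9 TPM (adjusted p = 0.381). None of 18 tissue Treg genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.831). Il10 (1218 ± 253 and 1080 ± 122 TPM) and the amphiregulin gene Areg (547 ± 65.6 and 581 ± 62.5 TPM) did not pass (adjusted p = 0.731 and 0.782).

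Among 15 tested growth factor genes with paracrine roles, 1 fell over all genes and 3 adjusted over the list alone, and the list fell (median -0.69, or -0.42 without WT replicate 3, camera adjusted p = 0.000475, fry 0.0198, adjusted p = 0.151 with an estimated correlation). Jag1, a Notch ligand gene, fell to 11.9 ± 1.87 from 21.6 ± 4.38 TPM (log2 -0.80, SE 0.17, adjusted p = 0.0453). Tgfb3, a transforming growth factor beta gene (chromosome 12, 86056743 to 86079041), was at 0.531 ± 0.0971 TPM in KO and 2.17 ± 0.788 TPM in WT. Its change did not pass over all genes (log2 -1.02, SE 0.29, adjusted p = 0.138), with a mean of 16.8 tags per KO library and 65.0 per WT library. Its exact two-sided permutation p, not adjusted for the number of genes, was 0.0179, the smallest possible. That test was not planned in advance, and 8.5% of the genes tested in Treg cells had no overlap between groups. Tgfb3 was 62.3 TPM on average in HFSC. Tgfb1 was at 114 ± 13.5 and 108 ± 21.5 TPM (adjusted p = 0.853). Jag1 averaged 79.6 TPM in HFSC, so it is among the genes left out of the fit without genes higher in HFSC. The settings that ended its call include those without KO replicate 1, 2, 3 or 5 or WT replicate 2 or 3, with a pseudocount of 0.1 and with no filter on low values.

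The largest differences were in transcripts of other skin cells, which were more abundant in the WT libraries. Krt15, a basal keratin gene of the follicle, was at 164 ± 68.5 TPM in WT and 6.75 ± 7.61 TPM in KO (log2 -4.76, SE 0.55, adjusted p = 0.00214). The neutrophil genes S100a9 and S100a8 (log2 -4.91 and -4.74), Krt5 (-3.49), Krt17 (-3.80), Dmkn (-4.19), Anxa8 (-3.55) and Ptn (-3.42) fell as well. Of 10 basal keratinocyte genes 7 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 3.36e-11, fry 0.0032, adjusted p = 0.0747 with an estimated correlation). Of 13 macrophage and monocyte genes 5 fell over all genes and 10 adjusted over the list alone, Cd14, Mrc1, Fcgr1 and Lyz2 among them (camera adjusted p = 6.97e-09, fry 0.00527, adjusted p = 0.0747 with an estimated correlation). The median keratinocyte level relative to HFSC was 1.05% to 1.56% in WT and 0.076% to 0.349% in KO libraries. These transcripts moved with the groups beside each lower gene group above. Without WT replicate 1 or 3 the calls of Krt5, S100a9, S100a8, Cd14, Mrc1, Fcgr1 and Lyz2 were lost. The call of Lyz2 was also lost without KO replicate 1 or 2, that of Ptn without WT replicate 3, and that of Krt17 was lost with any library left out except KO replicate 3. A robust prior ended the calls of Krt5, Krt17, Anxa8, S100a8, S100a9 and Lyz2, and a pseudocount of 0.1 ended those of Krt17, S100a8 and S100a9. No filter on low values and sample weights each ended those of Krt17, S100a9 and Lyz2, and quantile scaling ended that of Fcgr1.

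**Figure D2:**
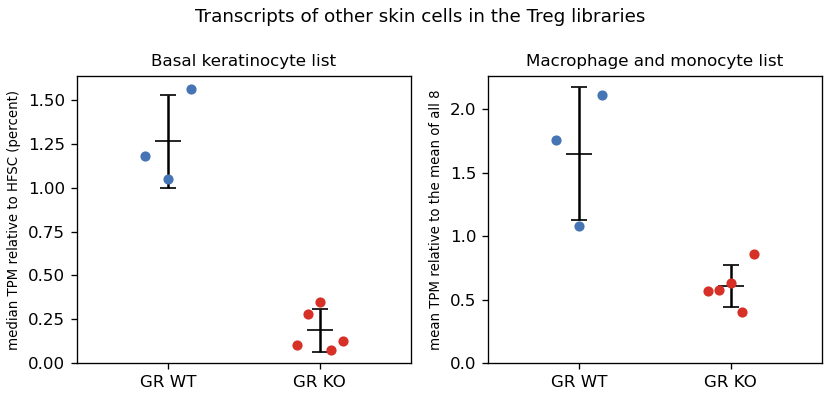
Level of basal keratinocyte genes relative to their mean in HFSC (left, percent) and mean relative level of macrophage and monocyte genes (right, 1 is the mean of all 8 libraries) in each Treg library, with bars for mean and SD (n = 3 WT and 5 KO). Every WT library lies above every KO library in both panels, from 1.05% to 1.56% against at most 0.349% for keratinocyte genes.

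Interferon response transcripts were also lower in Treg GR KO: of 21 tested genes 1 fell over all genes and 11 adjusted over the list alone (camera adjusted p = 1.39e-08, fry 0.0733, adjusted p = 0.227 with an estimated correlation). In the same libraries the macrophage and monocyte list had a median of -1.35 and the basal keratinocyte list of -2.19. Oasl2, an antiviral gene, fell to 2.20 ± 1.22 from 8.96 ± 2.23 TPM (adjusted p = 0.0196), a call lost without WT replicate 1 or 3. Higher in KO were the chemokine receptor genes Cxcr6 (339 ± 34.9 against 179.5 ± 22.5 TPM, log2 0.92, SE 0.11, adjusted p = 0.00291) and Ccr10 (46.3 ± 7.52 against 26.7 ± 4.32 TPM, adjusted p = 0.0412). Reep5 (log2 0.94), Stard4 (0.97), Srp19 (0.78), Prelid2 (1.09), Bri3 (0.76) and Ubald2 (0.70) rose too. The calls of Ccr10, Bri3 and Ubald2 were lost with any library left out except KO replicate 4 and that of Prelid2 with any except KO replicate 2. Those of Ccr10 and Prelid2 were also lost with quantile and median ratio scaling. With no filter on low values all 4 calls were lost. Those of Bri3 and Ubald2 were lost with a pseudocount of 0.1, that of Bri3 with a pseudocount of 5, and those of Bri3 and Prelid2 with voom. Conventional T cell genes rose as a list (camera adjusted p = 0.000291, fry 0.0152, adjusted p = 0.0747 with an estimated correlation), with no member past over all genes or adjusted over the list alone. The G2/M list rose by camera (adjusted p = 0.00296, fry 0.248, adjusted p = 0.321 with an estimated correlation, and lost without KO replicate 1 or WT replicate 2 and with a mean of at least 5 TPM), again with no member past either way.

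Over 11579 tested genes, limma called 175 in Treg cells, 23 higher and 152 lower, and 1630 had an unadjusted p under 0.05, where chance gives 579. All KO libraries lay above all WT libraries for 396 genes and below them for 591, together 8.5% of genes, where chance gives 3.57%. Both chance figures are averages that a single grouping of the libraries can exceed by chance, since genes move together. Other groupings were not counted in this way. Of the 32 lists tested, 23 passed camera, 13 passed fry and 0 passed camera with an estimated correlation (lowest adjusted p = 0.0747). Without WT replicate 1 the gene count was 107 and without WT replicate 3 it was 84, and without the genes at least 5 times higher in HFSC, an alternative chosen after seeing the data, it was 74, all among the 175, of which 100 were still tested. Higher genes went from 23 to 11 in that fit, with Bri3, Ccr10, Prelid2 and Ubald2 among the calls lost. Taking out called genes can itself raise the adjusted p of the genes that remain. Nr3c1 kept its log2 change of -0.711 while its adjusted p went from 0.0722 to 0.1. The lost calls therefore do not show that the higher genes depend on the genes left out.

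In HFSC from GR KO mice, cholesterol synthesis genes rose as a list by camera, and single genes rose beside them. Elovl6, a fatty acid elongase gene, rose to 1691 ± 223 from 756 ± 109 TPM (SD, n = 3 each, log2 1.16, SE 0.15, adjusted p = 0.0413), and Mfsd2a, a lysophospholipid transporter gene, to 114 ± 7.83 from 41.9 ± 8.53 TPM (log2 1.44, SE 0.16, adjusted p = 0.0413). The ceramide genes Cers4 (log2 0.85) and Acer1 (136 ± 15.4 against 67.4 ± 8.72 TPM) and the adipogenic gene Adig (1.34) rose too. Of 20 cholesterol synthesis genes 1 rose over all genes, Cyp51 (189 ± 6.68 against 112 ± 6.997 TPM, log2 0.75), and 18 adjusted over the list alone, Fdps (log2 0.60), Fdft1 (0.70) and Hmgcs1 (0.65) among them. The list's median was 0.70 (camera adjusted p = 2.69e-17, fry 0.129, adjusted p = 0.456 with an estimated correlation). Sebocyte and adipocyte genes, a list for another cell type of the follicle, moved with it: of 8 tested, 0 rose over all genes and 6 adjusted over the list alone (median 0.87, camera adjusted p = 3.72e-05, fry 0.129, adjusted p = 0.456 with an estimated correlation), with Scd1 at 4500 ± 422 and 2450 ± 594 TPM. WT replicate 1 stood apart from the other 5 libraries on the first principal component (59.8 against -17.7 to -4, 37.7% of the variance). It was lowest for both lists (mean log2 value 6.45 against 6.80 and 6.85 in the other WT libraries for cholesterol synthesis, 5.63 against 6.22 and 6.17 for sebocyte and adipocyte genes). Without it the medians were 0.61 and 0.69.

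Glucocorticoid receptor targets were higher in these HFSC, beside the sebocyte and adipocyte list at a median of 0.87 in the same libraries. Klf9, a Krüppel-like factor gene, rose to 83.1 ± 5.16 from 45.1 ± 3.46 TPM (log2 0.87, SE 0.11, adjusted p = 0.0413). Fkbp5 was at 109 ± 21.7 and 58.6 ± 5.80 TPM (adjusted p = 0.0689), with Errfi1 and Txnip at log2 0.90 and 0.73 (adjusted p = 0.0565 and 0.0754). Of 23 tested targets 1 rose over all genes and 8 adjusted over the list alone (median 0.41, or 0.25 without WT replicate 1, camera adjusted p = 7.45e-08, fry 0.129, adjusted p = 0.456 with an estimated correlation). Immediate early genes, in the same libraries, rose as a list with 0 of 20 past over all genes and 8 adjusted over the list alone, Egr3, Klf2, Ier3 and Atf3 among them (median 0.29, camera adjusted p = 9.5e-07, fry 0.129, adjusted p = 0.456 with an estimated correlation). Plk3, a stress-responsive kinase gene, and Aldh1a7 rose as single genes (log2 0.95 and 1.15).

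**Figure D3:**
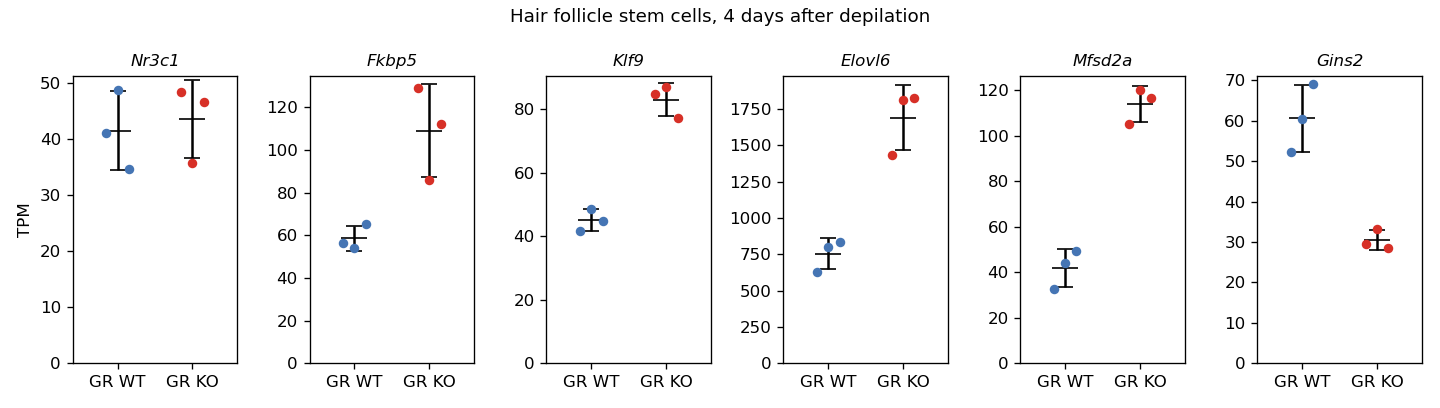
Transcript levels in TPM (y axis) of 6 genes in each HFSC library, with GR WT in blue and GR KO in red (n = 3 each), where bars give the mean and SD. Fkbp5, Klf9, Elovl6 and Mfsd2a lie higher and Gins2 lower in every KO library than in every WT library, while Nr3c1 overlaps.

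Cell cycle transcripts were lower in HFSC from GR KO mice, the libraries with the higher sebocyte and adipocyte list (median 0.87). Ung, which encodes uracil-DNA glycosylase, fell to 18.2 ± 1.96 from 39.1 ± 3.59 TPM (log2 -1.07, SE 0.14, adjusted p = 0.0413), and Gins2, a replication gene, to 30.5 ± 2.47 from 60.6 ± 8.35 TPM (log2 -0.96, SE 0.14, adjusted p = 0.0494). Of 22 S phase genes 2 fell over all genes and 17 adjusted over the list alone (median -0.50, camera adjusted p = 1.56e-11, fry 0.129), and of 22 G2/M genes 0 fell over all genes and 6 adjusted over the list alone (median -0.43, or -0.27 without WT replicate 3, camera adjusted p = 2.14e-08, fry 0.192). Both lists had an adjusted p = 0.456 with an estimated correlation. Mki67, a proliferation marker gene, was at 97.3 ± 19.6 and 128 ± 21.4 TPM (adjusted p = 0.291). Hedgehog targets fell as a list, with 0 of 7 past over all genes and 3 adjusted over the list alone, Mycn, Gli1 and Ptch1 (camera adjusted p = 0.00167, fry 0.199, adjusted p = 0.456 with an estimated correlation). Interferon response genes fell as a list with 0 of 13 past either way (camera adjusted p = 0.036, fry 0.129, adjusted p = 0.456 with an estimated correlation), a call lost without KO replicate 1 or 3 or WT replicate 1 or 2 and with a mean of at least 5 TPM. Selenom fell as a single gene (25.1 ± 2.16 against 51.3 ± 3.22 TPM), and Lgals1, B9d1, Tbx1, Dxo and Polr2h had values from -1.08 to -0.53 that did not pass.

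Stem cell identity transcripts did not pass over all genes. Cd34 was at 169 ± 49.6 and 126 ± 20.7 TPM, Itga6 at 109.5 ± 5.86 and 105 ± 19.6, Krt15 at 4026 ± 560 and 5558 ± 1491, and Lgr5 at 84.3 ± 19.8 and 78.8 ± 16.7 (KO and WT, SD, n = 3 each, adjusted p from 0.308 to 0.865). Of 20 bulge stem cell genes 0 passed over all genes and 3 fell when adjusted over the list alone, Tbx1, Nfatc1 and Lhx2 (camera adjusted p = 0.0739). The TGF-beta and SMAD targets did not pass as a list (camera adjusted p = 0.561). Of 19 tested, Cdkn1a, a cell cycle inhibitor gene, rose over all genes (153 ± 10.4 against 89.0 ± 6.04 TPM), and adjusted over the list alone 1 rose and 1 fell. Smad7 was at 13.6 ± 0.840 and 13.8 ± 0.168 TPM, and Tgfb2 at 4.21 ± 0.484 and 6.54 ± 1.62 TPM (adjusted p = 0.971 and 0.32).

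**Figure D4:**
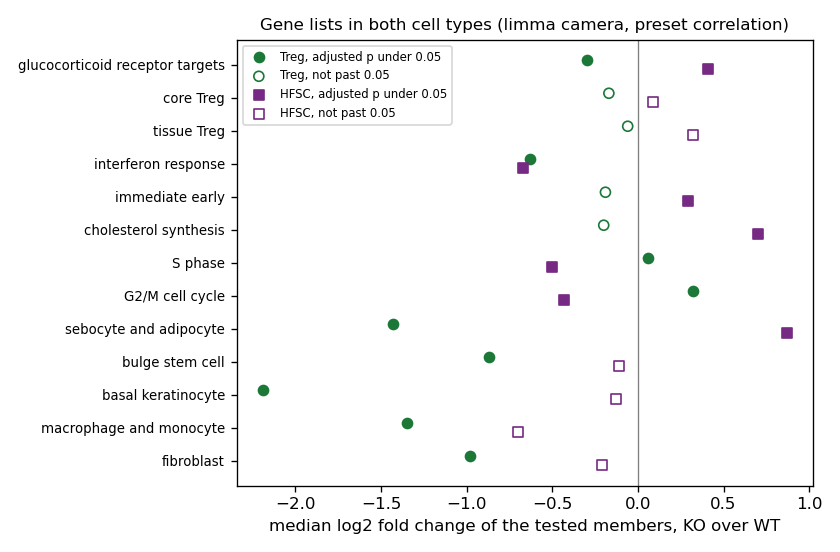
Median log2 fold change, KO over WT, of the tested members of 13 gene lists (x axis) in Treg cells (green circles) and HFSC (purple squares), filled where camera with a preset correlation gave an adjusted p under 0.05. Glucocorticoid receptor targets lie at -0.30 in Treg cells and 0.41 in HFSC, and interferon response genes lie below 0 in both.

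Over 12493 tested genes, limma called 22 in HFSC, 18 higher and 4 lower (the small RNA gene Snora52, named after its values were seen, with Ung, Gins2 and Selenom), 241 at an adjusted p of 0.1, and 2074 had an unadjusted p under 0.05, where chance gives 625. All KO libraries lay above all WT libraries for 1339 genes and below them for 1594, together 23.5% of genes, where chance gives 10%. Both chance figures are averages. Genes move together, so a single grouping of the libraries can exceed them by chance, and other groupings were not counted in this way. Of the 28 lists tested, 8 passed camera and 0 passed camera with an estimated correlation or fry. The gene count was 4, 1 and 0 without KO replicates 1, 2 and 3, and 2, 5 and 5 without WT replicates 1, 2 and 3. The call of Mfsd2a was lost in 4 of these 6 fits and those of Elovl6, Aldh1a7, Adig, Acer1, Cers4, Cyp51, Klf9, Plk3, Cdkn1a, Ung, Gins2, Selenom and Snora52 in all 6. These calls, Mfsd2a's too, were all lost with no filter on low values and that of Gins2 with a pseudocount of 0.1. Voom also ended that of Snora52. Other settings gave 2 to 584 genes, the 584 with sample weights (314 higher and 270 lower).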

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

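All 3 weighings of patterns below include tests chosen or revised after their result was seen: the sebocyte, keratinocyte, macrophage and Tgfb3 tests were chosen afterwards, the first of the sebocyte and keratinocyte tests were replaced after their results were seen, and the margins of 2 SE for the chromosome 18 and time of day tests were added after the first values were known. The tests on splits of the libraries, on the shallow library, and the gene set of the chromosome 18 test were written beforehand.

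Values far from the rest of their group were looked for in the 5 Treg GR KO libraries, in 104 genes and 32 lists, where chance gives about 5.2 and 1.6 and 17 and 1 were found. Replicate 3 stood above the other 4 libraries for keratinocyte genes: Krt15 at 20.2 TPM, Dmkn at 14.3, Krt17 at 25.4, Ptn at 5.14, Calml3 at 3.68, Spink5 at 1.83, Sbsn at 18.7 and Krt6a at 4.00 TPM. The same library was highest for Penk (75.3 TPM) and for the S phase list (mean log2 value 3.97, the others 3.82 to 3.85). Replicate 1 was highest for Ube2c (11.6 TPM), Id1 (6.27) and Cldn5 (2.92), replicate 2 for Krt79 (9.68), Junb (2750) and Mgst1 (21.6), and replicate 5 for Ptgs2 (5.63) and H2-Aa (131 TPM).

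The change with genotype went opposite ways in the Treg and HFSC tables, with no overlap between groups in either, for 7 of 61 genes and lists examined. These differences were not tested, since the tables were made separately and the cells were taken on different days. The ranked genes among the 61 had been picked for no overlap in 1 table, so 7 of 61 has no chance share to set beside it. Anxa8 and Elovl6 averaged 896 and 1220 TPM in HFSC, and the sebocyte and adipocyte list is of other skin cells. Their fall in the Treg libraries is therefore not shown to be a change in Treg cells. HFSC minus Treg differences in the log2 change were 0.86 for the glucocorticoid receptor target list (-0.47 in Treg, 0.38 in HFSC, means over members), 2.02 for the sebocyte and adipocyte list, 1.72 for Tsc22d3, 1.54 for Fkbp5, 3.98 for Anxa8, 2.55 for Elovl6 and 1.78 for Klf9.

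Lower transcripts in Treg GR KO could come from loss of the receptor or from RNA of other cells in the WT sorts, which were gated on the Treg reporter. RNA of keratinocytes and of macrophages was tested by whether a target rises with the list of that cell type within groups. For Cxcr4, Il7r and Tsc22d3 the upper bound of the slope was at most 17.1% (keratinocytes) and 7.9% (macrophages) of the slope between groups. No rise with either list was thus seen for them. Their slopes within groups were negative (for Il7r -116, SE 39.9, with keratinocytes and -181, SE 24.8, with macrophages). Other variation within groups could therefore mask a contribution, and neither RNA is excluded. RNA of neutrophils was not tested in this way. For Mt1 the bounds were 102.2% and 112%, and both stay open. Earlier versions, a macrophage sum of TPM of which Ccr2 made up 79.1% and a prediction from the HFSC profile (at most 16%), would have excluded all 4 genes, and the 3 genes were grouped after those results were known. That prediction reached 50% of the difference for 11 of 152 lower genes and gave 26.1% for Krt15, so a low value excludes nothing. Of the lower genes, 75 are at least 5 times higher in HFSC than in the Treg KO libraries. A fall in KO itself helps a gene to meet that rule, so the 75 cannot be counted as genes of keratinocyte origin. For Tgfb3 the keratinocyte prediction covered 32.6% of the difference (22.9% to 66.0% over the quartiles of the list). Subtracting instead the level found in each library left 0.966 of 1.64 TPM, or 0.0657 TPM at the upper quartile. With the median, every WT library stayed above every KO library (exact two-sided permutation p = 0.0179 over 56 assignments, not adjusted for the number of genes). The upper quartile took more than some libraries held, leaving -0.0782 in KO replicate 2, -0.201 in KO replicate 3 and -0.124 TPM in WT replicate 1. The true share is not known, so keratinocyte RNA and loss of the receptor cannot be told apart for this gene. The first rule, on the median alone, would have favoured loss of the receptor.

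Of the 23 genes higher in Treg GR KO, 4 lie within 10 Mb of Nr3c1 on chromosome 18 (Stard4, Srp19, Reep5 and Prelid2; 0.23 expected, Fisher's exact test p = 7.56e-05 over 117 genes in the window, a pattern noticed in the data). Variants inherited with the floxed allele would move these genes in HFSC as well, and loss of the receptor in Treg cells alone would not. The median HFSC change in the Treg direction was 0.38 over the 5 called genes of the window measured in HFSC, with 4 of 5 moving by 0.2 or more and Spink5 not. The SE used with it, 0.13, is that of a mean over these neighbouring genes. It leaves out the spread between libraries, which for Prelid2 alone gave an SE of 0.58. Neither explanation is excluded, and they cannot be told apart. Restricting the test afterwards to the 4 higher genes gave 0.44 and would have met the prediction for variants, and without the margin the 5-gene value would have excluded loss of the receptor. None of the 4 passed the threshold in HFSC, the call of Prelid2 in Treg cells was lost in 7 of 8 fits with a library left out, and Stard4 also belongs to the cholesterol list that rose there.

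In HFSC, cholesterol synthesis and receptor target genes were higher and cell cycle genes lower in KO. The shallow WT replicate 1, which also stood apart on the first principal component (59.8 against -17.7 to -4), does not account for the camera calls of the lists, since all 4 tested (cholesterol synthesis, receptor targets, S phase and G2/M) kept direction and camera call without it, though the receptor target median went from 0.41 to 0.25. With all libraries, none of the 4 passed with an estimated correlation (camera adjusted p = 0.456) or by fry (adjusted p from 0.129 to 0.192). More sebocytes in the KO sorts, which were gated on CD34 and integrin alpha 6, stay possible for the cholesterol synthesis genes. The 6 sebocyte genes had a median change of 0.80 against 0.70 for cholesterol synthesis, with Fa2h at 1250 and 626 TPM and Elovl3 at 345 and 181. None of these genes passed (limma adjusted p from 0.0785 to 0.757). The test was chosen after the sebocyte and adipocyte list had been seen higher in these libraries. It cannot tell more sebocytes from higher lipid genes in the sorted cells themselves. For the receptor targets sebocytes stay open with no test of their own, and for the cell cycle genes they stay open as well. Basal keratinocyte and bulge genes lay above the cell cycle genes by 0.33 in medians over genes. In library means the difference was 0.37 (SE 0.19), and both values are under 2 SE. A first version with an SE over genes (0.07) would have excluded sebocytes. Harvest at another time of day stays open: the clock arms moved apart by 0.22 in medians over genes, set beside an SE of 0.23 from library means. Without the margin, the 0.22 would have excluded another harvest time, and all 9 genes of the Dbp arm had positive changes.

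Other splits of the libraries bear on the counts. In Treg cells, 1 of 56 splits, the real one, gave as many as 175 genes (highest other 2) and 1 of 56 as many as 23 lists (highest other 20). A share of 1 of 56 is the smallest possible here, which argues against chance for the gene count without excluding it. For lists, camera at the preset correlation also called up to 20 in splits that mixed the genotypes. The count of 23 lists is therefore weak evidence against chance, and camera's list p-values need the other list tests beside them. The 6 HFSC libraries make only 10 splits, too few for a share under 0.05: the real split gave 22 genes (highest other 3) and 8 lists (highest other 6), and 1 of 10 gave as many in each case.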

How the results depend on the processing

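Alternatives chosen after seeing the data were voom on recovered tags and the fits without small RNA genes or without genes higher in HFSC. The count test planned for raw counts was not run, since the tables hold TPM. All genes called in the reported fits that a setting tested kept their sign in it, and the cause of the changes below was not tested unless named. Treg calls (175) became 274 at a threshold of 0.1, 74 without the 1430 genes higher in HFSC, which removes 75 of the called genes and leaves 100, and 84 to 186 with a library left out. Treg lists (23) became 13 with fry and 0 with an estimated correlation. The muscle list, called lower, turned direction without WT replicate 3 (adjusted p = 0.466, range with a library left out 0.00293 to 0.466). Nr3c1 in Treg (log2 -0.71) stayed lower in all 20 alternatives and passed with median ratio scaling (-0.67), voom (-0.65), without small RNA genes (-0.71), with the replicate block and without KO replicate 4, and ranged from -0.86 to -0.63 with a library left out. HFSC calls (22) became 241 at a threshold of 0.1, 2 with no filter on low values, 48 with at least 5 TPM, 58 with quantile and 69 with median ratio scaling, 584 with sample weights (53.8% higher), 51 with a robust prior, 483 with voom (49.7% higher, against 81.8%), 190 without the 402 small RNA genes, and 0 to 5 with a library left out. HFSC lists (8) became 0 with fry and 0 with an estimated correlation. Nr3c1 in HFSC was -0.088 with sample weights and ranged from -0.05 to 0.20 with a library left out, and passed in none of 17 alternatives. For the 109 other Treg genes, 1904 of 2117 values kept direction and side of the threshold and 186 lost the call; for the 59 HFSC genes, 744 of 993 did, 129 lost the call and 112 gained one. Replicate numbers did not pair the samples: correlations of deviations for numbers 1, 2 and 3 were 0.17, 0.087 and -0.117 in Treg and 0.016, 0.062 and -0.042 in HFSC, and not every library correlated best with its own number. With the replicate block, Treg calls were 78, HFSC calls 66 and Nr3c1 in Treg -0.90 (adjusted p = 0.0406), and among the genes named in the text it ended the calls of Jag1, Stard4, Srp19, Prelid2, Bri3, Ubald2, Ccr10, Oasl2, Krt5, Krt17, Dmkn, Mrc1, Fcgr1, Il1b, Krt6a, Mgst1, Elovl3, Il2ra, Snora20, Mir3960, Mir703 and Mir7091 in Treg and of Ung, Gins2, Plk3 and Snora52 in HFSC. In Treg, numbers 4 and 5 exist only in KO, so with the block these libraries add nothing to the genotype effect. The Treg block fit thus compares KO and WT only for numbers 1, 2 and 3, and its lost calls need not reflect pairing. Its pass for Nr3c1 also overlaps the pass without KO replicate 4. HFSC WT replicate 1, at 4.5 M tags, limits what low genes can show.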

Other observations

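The gene list tests here were fixed before the data were examined, and the fits without small RNA genes were chosen only after the result was seen. Treg libraries differed in transcripts of further skin cells. Fibroblast genes fell as a list in GR KO (median -0.98, or -0.64 without WT replicate 3, camera adjusted p = 0.000291, fry 0.0924, adjusted p = 0.227 with an estimated correlation), with 0 of 11 past over all genes and 1 adjusted over the list alone, Lum (4.00 ± 2.98 in KO, 11.04 ± 0.857 TPM in WT). Of 7 neutrophil genes 3 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0143, or 0.124 without WT replicate 1, fry 0.0136, adjusted p = 0.151 with an estimated correlation), and of 19 NF-kB targets the cytokine genes Cxcl2 (121 ± 7.30 to 26.6 ± 9.11 TPM) and Il1b (237 ± 80.4 to 50.1 ± 16.1 TPM) fell over all genes, while adjusted over the list alone 1 rose and 3 fell.

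Small RNA genes made up 378 of the tested Treg genes, 4 of them called (Snora20, Mir3960 and Mir703 higher, Mir7091 lower), and 402 of the tested HFSC genes, 5 of them called (Snord98, Mir22, Mir7093 and Mir1892 higher, Snora52 lower). These genes are named here after their values were seen. With a library left out, the calls were lost in 5 of 8 fits for Mir3960, 6 of 8 for Mir703, 3 of 8 for Mir7091 and 0 of 8 for Snora20. In HFSC they were lost in 1 of 6 fits for Snord98 and in 6 of 6 for the other 4. Voom, which works on the tags, ended the calls of all 9. Leaving out all small RNA genes, called or not, raised the calls from 175 to 247 in Treg cells and from 22 to 190 in HFSC. In HFSC 17 of the 22 called genes were other genes, and the 17 were all called again.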
